A study of Mus musculus with 18 samples.

How the data were processed

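Transcript levels were measured in J774.A1 cells with 1-colour CodeLink mouse whole-genome arrays and biotin-marked target. Per the labels, the cells were incubated in serum-free medium with latex beads of 1 µm that carried avidin, Fc fragment, LPS or mannan, for 30 or 60 min, and untreated cells were the control. There were 18 arrays in 9 groups of 2, and each group was 1 bead type at 1 time. The replicates were separate cell samples, but whether they came from separate cultures is not given in the sources used here, so each p-value measures the spread between these samples.

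The authors scanned the arrays and extracted the spots with CodeLink EXP 4.0. Per the file headers, each array's file gives the mean spot intensity and the median local background intensity of 35557 spots, a background-subtracted intensity, and a normalised intensity. The deposited normalised intensity is the background-subtracted intensity divided by 1 factor per array close to the array's median, and the deposited value tables hold the same normalised intensity. The authors also gave a GeneSpring matrix, whose deposited values are a background-subtracted intensity and a linear ratio with a floor of 0.01. The version of GeneSpring and the steps behind that ratio are not given in the sources used here. None of the deposited values was on a log2 scale, and the log2 values described here were computed from the intensity.

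Spots flagged by the software as contaminated, masked or irregular were set to missing. Between 2.97 and 9.46 percent of the probes were missing on an array. Local background was removed with the normexp method at an offset of 50, and the arrays were then quantile normalised and put on the log2 scale. Control spots (320 negative and 300 positive) were left out, which left 34937 probes. A probe was kept if both arrays of at least 1 group had it flagged good or saturated, which 23288 did. Probes were tied to gene symbols by RefSeq accession: 14818 had 1 symbol and 20119 had none. Of several probes for 1 symbol the one with the highest mean was used. This gave 22659 features, 10620 with a symbol and 12039 without. Values were present on all 18 arrays for 8224 of them, so n differed between genes, and results on 1 array in a group are marked. Spots above background made up 57.9 to 60.2 percent of the probes on 17 arrays and 49.6 percent on the other. Where all spots of a group were at background, the fold is a lower bound against the level above which spots were flagged good.

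Group means were fitted to all 18 arrays in 1 linear model with limma 3.58.1 in R 4.3.3, and the files were read with the data.table package, version 1.17.8. Each contrast was tested with limma's moderated test and adjusted by the Benjamini-Hochberg method over the features tested in it, with a threshold of 0.05 and no minimum fold. A lone array in a group is assumed to vary like the other groups. The 24 tests set each bead group and their mean against untreated cells, each ligand against avidin at each time, the 4 bead types against each other by an F-test at each time, 60 against 30 min for each bead type, and that change with time between each ligand and avidin. Gene lists, fixed by hand, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Members were also adjusted over the list alone.

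The comparisons, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per comparison and direction, the 10 genes past the threshold with the largest change whose arrays did not overlap between the groups, up to 4 members of each list, 16 fixed genes, and the 20 genes with the highest F. Features without a symbol were counted but not named. The text prints part of the genes that the rule named, and this choice among them was made after their values were seen. Genes outside the rule are marked where they appear.

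The alternatives were an offset of 16, median scaling in place of quantile normalisation, the deposited normalised intensity, the GeneSpring values, no filter, a filter on spots above background on all 18 arrays, replicate number as a block, an intensity trend with robust estimation, fits within a slide run, and leaving out each array. The order of the slide numbers gives 3 slide runs. Whether these were hybridised separately is not given in the sources used here, so a fit within a run, or with run as a block, removes a run difference only if the slide numbers mark it. Each group lies wholly in 1 run, so runs and groups could be separated only for pairs of groups in the same run. Keeping the contaminated spots, and leaving the dim array out of every comparison, were added after the data were seen. The 36 pairs of groups gave correlations between the replicates' deviations from -0.261 to 0.168 (median 0.014), so the replicate numbers were not treated as pairs.

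The steps were tested on simulated data with 200 changed genes in each of 5 simulations. At 2 arrays against 2, changes of log2 0.585, 1 and 2 were recovered in 28.6, 87.2 and 99.4 percent of cases at the array values of Fc beads at 60 min, with 5.1 percent of calls false, and in 24.6, 87.2 and 99.7 percent at those of LPS beads at 60 min, with 4.8 percent false. Of 65 simulated comparisons without a change 1 had a call, and 1 of 1755 simulated list tests was called. The simulated genes varied independently of each other, and no simulated array was dim. These rates therefore do not cover correlated genes, on which the list tests depend, or an array like the dim one. Each of these 2 simulated groups held 200 changed genes, while the real bead groups gave 0 to 93 calls against untreated cells. Fewer changed genes make the adjusted threshold stricter, so the rates can overstate recovery in the real comparisons. The number of arrays limits the precision: changes under about a doubling were often missed. Some above a doubling did not pass either, such as Cxcl2 at 60 min of LPS beads (log2 1.15). The phagosome maturation part of the series was not analysed here.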

Results

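Transcripts were measured in J774.A1 cells, a mouse macrophage-like line, that had taken up latex beads of 1 µm. The beads carried 1 of 4 ligands. Avidin beads had no added ligand beyond the avidin itself, per the labels, and whether avidin binds a receptor was not tested. The Fc fragment of mouse IgG binds Fc gamma receptors. Lipopolysaccharide (LPS) from Klebsiella pneumoniae signals through Toll-like receptor 4. Mannan, a yeast polysaccharide, is bound by mannose receptors and other lectins. Cells were harvested after 30 or 60 min with beads, and untreated cells served as the control. Each of the 9 groups had 2 cell samples, and each sample was hybridised to its own whole-genome array, which gave 18 arrays. The series asked how the receptor-ligand pair acts on phagosome maturation and on gene expression after receptor-mediated uptake. Only the gene expression part is described here.

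On 17 arrays, between 20234 and 21018 of the 34937 probes gave a signal above local background, and the median background-subtracted signal lay between 96.5 and 118 scanner units. Replicate 1 of avidin beads at 60 min stood apart, with 17330 probes above background and a median signal of 56.2. It is called the dim array below. The standard deviation of its log2 difference from its replicate was 0.427, against 0.200 to 0.273 in the other 8 groups. With 2 arrays per group, the number of arrays limited the precision of every value. Fold changes are given on the log2 scale with the standard error (SE) of the model, and n is 2 arrays in each group unless stated.

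**Figure D1:**
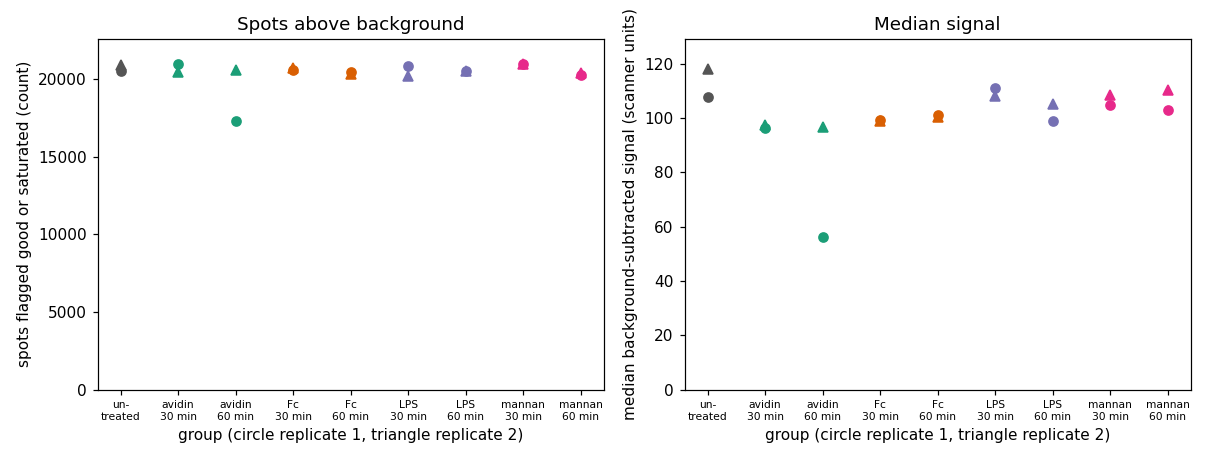
Number of probes flagged good or saturated (left) and median background-subtracted signal in scanner units (right) for each of the 18 arrays, by group; each point is 1 array, circles replicate 1 and triangles replicate 2. Replicate 1 of avidin beads at 60 min lies at 17330 probes and 56.2 units, and the other 17 arrays lie between 20234 and 21018 probes and between 96.5 and 118 units.

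Early inflammatory transcripts were higher after 30 min of Fc beads than in untreated cells, which lay in another slide run. Whether untreated cells had the same change of medium is not given in the sources used here. No comparison with untreated cells can therefore separate bead uptake from the medium. Cxcl2, a neutrophil-attracting chemokine, rose 7.64-fold (log2 2.93 ± 0.16, adjusted p = 2.69e-06), and Egr2, an immediate-early zinc finger transcription factor, rose 5.97-fold (2.58 ± 0.19, adjusted p = 8.58e-05). Ccl7, a monocyte-attracting chemokine, rose by 2.0 ± 0.17, and Csf2, which encodes GM-CSF, by 1.66 ± 0.20. Ier3, an early stress-response gene, rose by 1.45 ± 0.15, the cytokine gene Tnf by 1.20 ± 0.14, and the chemokine gene Ccl3 by 1.32 ± 0.16. Jun, a subunit of the AP-1 transcription factor, rose by 1.40 ± 0.16, Ptgs2, the inducible cyclooxygenase, by 1.46 ± 0.18, and Zfp36, an mRNA-destabilising protein that limits cytokine output, by 0.98 ± 0.13, each against 1 untreated array. Chac1, a glutathione-degrading enzyme that is a target of the integrated stress response, fell 2.88-fold (-1.52 ± 0.15, adjusted p = 0.000209). Klf10, an early-response transcription factor, fell by 0.73 ± 0.13 on the log2 scale.

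By fixed gene lists, 4 of 14 measured chemokines rose and none fell after 30 min of Fc beads (7 when adjusted over the list alone; median log2 0.39), with Ccl2 at 1.00 beside Cxcl2, Ccl7 and Ccl3. The list of inflammatory cytokines also holds the enzyme gene Ptgs2. Of its 12 measured members, 3 rose (3 over the list alone), namely Tnf, Csf2 and Ptgs2, while the interleukin gene Il1b stood at 0.31 ± 0.19 (adjusted p = 0.665). Of 18 feedback inhibitors of signalling, 2 rose, Zfp36 and Rgs1 (6 over the list alone). These 3 lists were shifted upward as sets by camera (adjusted p = 1.58e-09, 3.85e-05 and 6.12e-06), and each kept the call with an estimated correlation (adjusted p = 0.0291 for all 3). Of 20 immediate-early genes 3 rose and 1 fell (6 and 1 over the list alone; camera adjusted p = 9.81e-07, and adjusted p = 0.194 with an estimated correlation). Fos, of the same list, stood at 1.25 ± 0.25 with adjusted p = 0.112, on 1 untreated array, and passed without the dim array (adjusted p = 0.0239) and with the contaminated spots kept (0.00751).

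In all, 47 of 22265 features passed the threshold in limma at 30 min of Fc beads, 34 higher and 13 lower, of which 20 had no gene symbol and 14 rested on 1 array in a group. The count was 17 without untreated replicate 2 and 97 without the dim array, which does not belong to the comparison but enters the pooled spread. Of the 19 called genes followed through the alternatives, 10 kept the call in each leave-one-out fit that gave them a value, namely Cxcl2, Egr2, Ccl7, Csf2, Ier3, Jun, Tnf, Zfp36, Chac1 and the histone gene H2bc8. Jun and Zfp36 could not be tested without their lone untreated array. Klf10 lost it without any 1 of its 4 arrays (adjusted p up to 0.293), Ccl3 without untreated replicate 2 (0.0528), Ccl2 without that array or Fc replicate 1 (up to 0.105), and Ptgs2 without Fc replicate 1 (0.0537).

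**Figure D2:**
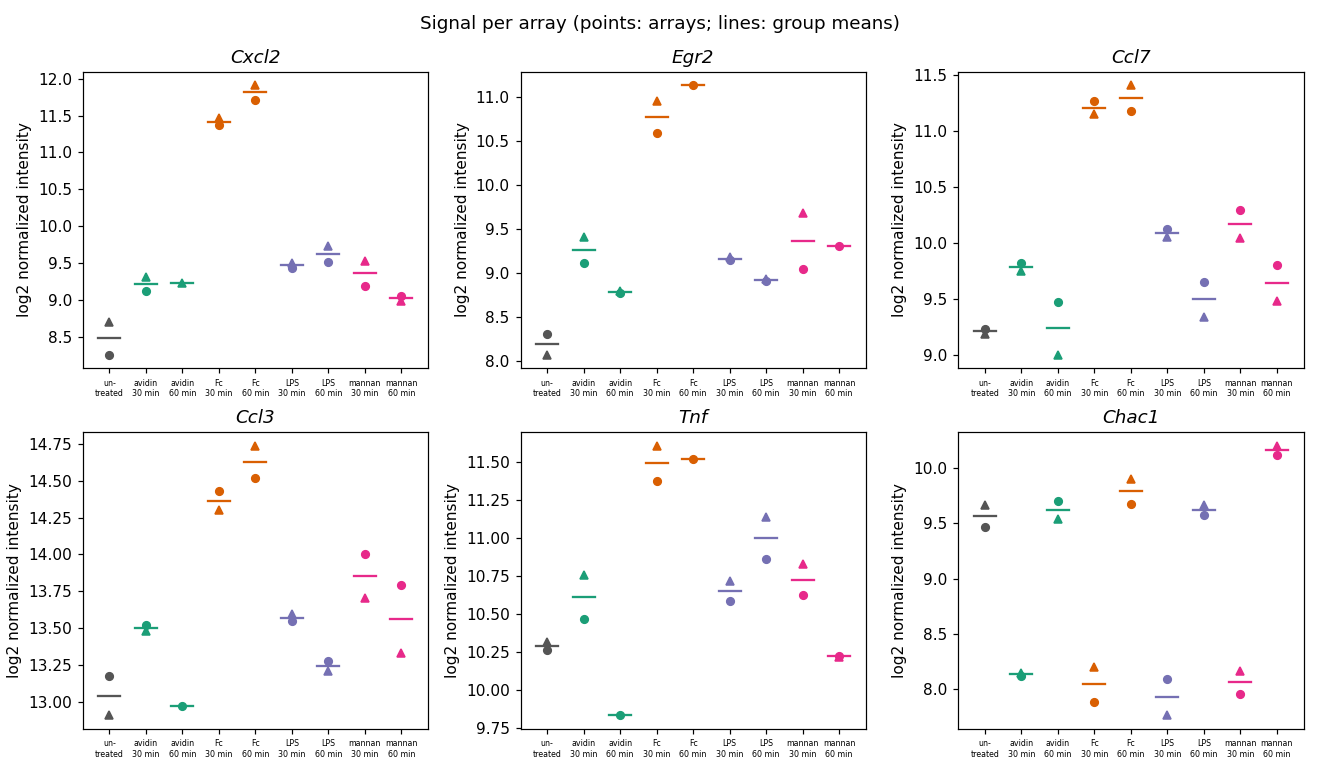
Log2 normalised intensity of 6 genes on each array, by group; points are arrays (circles replicate 1, triangles replicate 2) and lines are group means, and each panel has its own vertical range. Cxcl2 averaged 8.48 in untreated cells, 11.4 and 11.8 with Fc beads at 30 and 60 min, and 9.02 to 9.63 in the other bead groups; Chac1 averaged 7.93 to 8.13 in all bead groups at 30 min and 9.57 in untreated cells.

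After 60 min of Fc beads the same chemokine and cytokine genes stood high. Cxcl2 was 10.1-fold above untreated cells (log2 3.33 ± 0.16, adjusted p = 5.43e-07), and Ccl7 rose by 2.08 ± 0.17, Ptgs2 by 1.77 ± 0.18 (1 untreated array), Ccl3 by 1.59 ± 0.16 and Ccl2 by 1.23 ± 0.13. Egr2 rose by 2.94 ± 0.24 and Cd83, a costimulatory surface protein of activated antigen-presenting cells, by 1.26 ± 0.14, each on 1 Fc array. Ptger4, a prostaglandin E2 receptor, rose by 1.09 ± 0.13, and Ccrl2, an atypical chemokine receptor, by 1.17 ± 0.14. Tnf rose by 1.23 ± 0.17 on 1 Fc array, and Atf3, a stress-induced transcription factor, by 1.02 ± 0.16. Chac1 was no longer lower than in untreated cells (0.22 ± 0.15, adjusted p = 0.646).

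Of the 14 chemokines, 5 rose and none fell at 60 min of Fc beads (6 over the list alone; median log2 0.35; camera adjusted p = 6.61e-09, and adjusted p = 0.0533 with an estimated correlation). Of the 12 members of the cytokine list, Ptgs2 included, 3 rose (5 over the list alone). The list kept its camera call with an estimated correlation (adjusted p = 2.91e-06, then 0.0176). Camera also placed 5 more lists higher, the immediate-early genes (2 of 21 rose, 8 over the list alone; adjusted p = 1.49e-07), NF-kappaB targets (0 of 15, 3 over the list alone; 0.000101), feedback inhibitors (2 of 18, 3 over the list alone; 0.000101), antigen presentation (1 of 15, 2 over the list alone; 0.000484) and the Toll-like receptor pathway (0 of 16, 2 over the list alone; 0.0133). These 5 lost the call with an estimated correlation, at adjusted p = 0.115, 0.272, 0.0618, 0.106 and 0.298 in that order. In total 40 of 22063 features passed in limma, 30 higher and 10 lower. Between the times, 13 features rose and 3 fell against untreated cells at both 30 and 60 min of Fc beads, where independent lists of those sizes would share 0.045 and 0.00546. Both comparisons use the same 2 untreated arrays, which the values for independent lists leave out. Simulated unchanged groups against shared controls shared 0 calls at most. Such groups have almost no calls at all, so this 0 is no yardstick for the overlap. Their fold changes correlated at 0.513, against 0.521 here. With 2 untreated arrays the controls could not be split, so the part of the overlap due to shared arrays stays open.

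The count at 60 min of Fc beads was 16 without untreated replicate 2, 23 without untreated replicate 1 and 93 without the dim array. Calls for Cxcl2, Egr2, Ccl7, Ccl3, Ccl2, Ptgs2, Ptger4, Ccrl2 and Cd83 were kept in each leave-one-out fit that gave them a value. Egr2 and Cd83 could not be tested without their lone Fc array, nor Ptgs2 without its lone untreated array. Tnf lost its call without either untreated array (adjusted p up to 0.0881), and Atf3 without either untreated array or Fc replicate 2 (up to 0.222).

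Avidin beads, which carried no added ligand beyond the avidin itself, were set against untreated cells. After 30 min, Chac1 fell 2.7-fold (-1.44 ± 0.15, adjusted p = 0.00132). Id1, an inhibitor of basic helix-loop-helix transcription factors, rose by 1.02 ± 0.15, Ier3 by 0.92 ± 0.15 and Ptger4 by 0.81 ± 0.13, with adjusted p = 0.0484 for each. Hmox2, the constitutive haem oxygenase, fell by 0.81 ± 0.13 on the log2 scale, and Mrpl36, a mitochondrial ribosomal protein, by 0.91 ± 0.12. Of 21 immediate-early genes 1 rose (4 rose and 2 fell over the list alone), and 0 of 18 feedback inhibitors passed, none over the list alone either. Camera placed both lists higher (adjusted p = 0.0136 for each), and neither kept the call with an estimated correlation (adjusted p = 0.646 for each). In limma 15 of 22302 features passed, 5 higher and 10 lower. The count was 4 without avidin replicate 2, 5 without untreated replicate 2 and 66 without the dim array. Chac1 kept its call with each array of the comparison left out, whereas Id1, Ier3 and Hmox2 lost theirs without any 1 of the 4 arrays (adjusted p up to 0.294, 0.268 and 0.301), Ptger4 without either avidin array or untreated replicate 2 (up to 0.338) and Mrpl36 without avidin replicate 2 or either untreated array (up to 0.161).

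At 60 min of avidin beads, the named genes that fell included Rps24, a ribosomal protein (-0.94 ± 0.18), Smc4, a condensin subunit (-0.90 ± 0.18), and Cdkn1a, the cell cycle inhibitor p21 (-0.86 ± 0.15). Fbln2, an extracellular matrix protein, rose by 0.81 ± 0.11, Ptcra, the pre-T-cell receptor alpha chain, by 0.94 ± 0.14 and Inpp5a, an inositol phosphatase, by 0.85 ± 0.15. Tnf stood at -0.46 ± 0.17 (adjusted p = 0.221, and 0.039 with median scaling) on 1 avidin array. No list was called by camera. In limma 93 of 22266 features passed, 26 higher and 67 lower, and 34 of them had their avidin value on the dim array alone. Without the dim array 0 features passed in limma (2299 at an unadjusted p under 0.05), and without avidin replicate 2, which leaves the dim array alone, 3479 did. The count was 35 without untreated replicate 1 and 13 without untreated replicate 2. Each called gene named for this comparison lost its call without the dim array and without untreated replicate 2, and all but Fbln2 without untreated replicate 1 as well (adjusted p up to 0.293).

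After 30 min of LPS beads Chac1 was 3.12-fold lower than in untreated cells (log2 -1.64 ± 0.15, adjusted p = 0.000166), and Ier3 was higher by 1.04 ± 0.15 (adjusted p = 0.0421). Cxcl2 stood at 0.99 ± 0.16, with adjusted p = 0.064, and Tnf at 0.36 ± 0.14, with adjusted p = 0.645. Cxcl2 passed in 5 of 13 other settings (lowest adjusted p = 0.0223), among them without untreated replicate 2 (0.0382) and without the dim array (0.0296). Ier3 lost its call without any 1 of the 4 arrays (adjusted p up to 0.2). In limma 4 of 22060 features passed, 1 higher and 3 lower. The other 2 were a probe without a symbol (-1.63 ± 0.12) and Med11, a Mediator subunit, chosen here after its values were seen. Med11 fell by 6.76 ± 0.20 on the log2 scale, on a single LPS array whose spot was at background while its replicate was missing, and the drop was at least 74.3-fold against the level above background in untreated cells. Its call could not be tested without that array. The count was 11 without LPS replicate 2, 12 and 7 without untreated replicates 1 and 2, and 29 without the dim array, and no list was called by camera.

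After 60 min of LPS beads no single feature passed, with 0 of 22223 called in limma and 1152 at an unadjusted p under 0.05. Cxcl2 stood at 1.15 ± 0.16 (adjusted p = 0.159) and passed in 5 of 14 other settings (lowest adjusted p = 0.0198), among them without untreated replicate 2 (0.0202). Tnf stood at 0.71 ± 0.14 (adjusted p = 0.462) and Chac1 at 0.05 ± 0.15 (adjusted p = 0.995). As a set, 16 NF-kappaB targets were shifted upward (median log2 0.24; camera adjusted p = 0.000801), with 0 members past the threshold and 0 over the list alone. Camera also called the immediate-early genes and the Toll-like receptor pathway (adjusted p = 0.0281 for each) and the interferon response (0.0495), again with 0 members over the list alone. Adjusted p with an estimated correlation was 0.567 for the NF-kappaB, Toll-like receptor and interferon lists and 0.744 for the immediate-early list. Within the slide run that holds both groups, the NF-kappaB and immediate-early lists kept their camera calls (adjusted p = 0.000841 and 0.0312), while the Toll-like receptor (0.0569) and interferon lists (0.101) lost theirs. Leaving out LPS replicate 1 or 2 gave 6 and 12 features, and leaving out either untreated array gave 4.

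With mannan beads at 30 min Chac1 was 2.84-fold lower than in untreated cells (log2 -1.51 ± 0.15, adjusted p = 0.00144). The call was kept with each array left out and in a fit on the slide run that holds both groups (adjusted p = 0.00279). Cxcl2 stood at 0.88 ± 0.16 (adjusted p = 0.124) and Egr2 at 1.17 ± 0.19 (adjusted p = 0.101; 0.0174 without mannan replicate 1). Chemokines were shifted upward as a set, with 0 of 14 past the threshold and 3 over the list alone (median log2 0.15; camera adjusted p = 5.88e-05, and adjusted p = 0.495 with an estimated correlation). The unfolded protein and integrated stress response list was shifted downward, with Chac1 the member past the threshold (2 of 16 fell over the list alone; camera adjusted p = 0.0488), and the immediate-early list upward (0 of 20 past the threshold, 3 over the list alone; 0.0115). With an estimated correlation both stood at adjusted p = 0.731. Within the slide run, camera kept the chemokine and immediate-early calls (adjusted p = 0.0011 and 0.0276) and lost the stress response one (0.0734). In limma 2 of 22212 features passed, 1 higher and 1 lower, and the count was 23 and 28 without mannan replicates 1 and 2, 8 and 6 without untreated replicates 1 and 2, and 14 without the dim array.

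At 60 min of mannan beads, Tle6, a Groucho-family corepressor, rose by 2.53 ± 0.32 (adjusted p = 0.0172), at least 4.47-fold since all untreated spots were at background. Toporsl rose by 1.14 ± 0.13, at least 1.41-fold for the same reason, and Bicc1, an RNA-binding protein, by 1.28 ± 0.16 on 1 mannan array. In a fit on the slide run that holds both groups, the fold changes of Tle6, Toporsl and Bicc1 are the same by construction (2.53, 1.14 and 1.28). Each lost the call there (adjusted p = 0.0834, 0.0571 and 0.0571). Tle6 also lost the call without mannan replicate 1 or untreated replicate 2. Toporsl lost it without mannan replicate 1 or untreated replicate 1 (up to 0.0643), and Bicc1 without untreated replicate 2 (0.162). Chemokines (0 of 14 past the threshold, 2 over the list alone; median log2 0.25), the interferon response (0 of 18), antigen presentation (0 of 15, 1 over the list alone) and NF-kappaB targets (0 of 15) were shifted upward by camera (adjusted p = 0.00362, 0.0109, 0.0109 and 0.0339). With an estimated correlation they stood at adjusted p = 0.332, 0.332, 0.332 and 0.525, and within the slide run their camera calls were kept (0.0159, 0.0159, 0.0273 and 0.0273). In limma 6 of 22078 features passed, 5 higher and 1 lower, with 2 and 35 without mannan replicates 1 and 2 and 10 without the dim array.

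Averaged over the 8 bead groups, Cxcl2 rose by 1.42 ± 0.12 (adjusted p = 0.000603), Egr2 by 1.40 ± 0.15 and Ccl7 by 0.91 ± 0.12 against untreated cells. All 3 had their highest mean with Fc beads at both times, so the Fc groups weigh heavily in these averages. Cxcl2 averaged 11.4 and 11.8 with Fc beads at 30 and 60 min, and 9.02 to 9.63 in the other bead groups. Cst9, a cystatin-family gene, fell with a modelled change of -1.06 ± 0.13, which is no exact size since its spots were at background in every bead group; the bounds for single bead groups were at least 1.56-fold to at least 1.8-fold lower. Of 14 chemokines 2 rose (5 over the list alone; camera adjusted p = 2.55e-06), and of 16 immediate-early genes 1 rose (3 over the list alone; 2.55e-06). Camera called 7 lists, all upward, and 0 kept the call with an estimated correlation (adjusted p = 0.154 for chemokines and 0.158 for the immediate-early list). In limma 5 of 21148 features passed, 3 higher and 2 lower. The count was 3 without replicate 1 of Fc beads at 30 or 60 min or of LPS beads at 30 or 60 min, 15 without the dim array, 30 without avidin replicate 2 at 60 min and 19 without untreated replicate 1. Cxcl2 kept its call in the 17 leave-one-out fits that gave it a value, and could not be tested without avidin replicate 2 at 60 min. Egr2 lost it without untreated replicate 2 (adjusted p = 0.135), Cst9 without either untreated array (up to 0.143), and Ccl7 without either untreated array, LPS replicate 1 or Fc replicate 1 at 30 min (up to 0.272).

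Genes of the uptake machinery gave small values in every bead group. The Toll-like receptor gene Tlr4, the inhibitory Fc receptor gene Fcgr2b, the mannose receptor gene Mrc1, the lysosomal membrane gene Lamp1 and the phagosome GTPase gene Rab20 gave 40 values against untreated cells, from -0.31 to 0.46 with an SE of up to 0.29 and no adjusted p under 0.333. The 19 members of the Fc receptor pathway list were not shifted as a set with Fc beads (median log2 0.01 and 0.08 at 30 and 60 min; camera adjusted p = 0.857 and 0.296). Over all 22 comparisons with a direction, 14 of the 27 lists were never called by camera, with 0.06 as the lowest adjusted p. Those 14 included the Fc receptor pathway, lectin and scavenger receptors, the oxidative burst, glycolysis, ribosomal proteins, macrophage identity, and the markers of lymphocytes, granulocytes, fibroblasts and epithelial cells. The lysosome list was called in 2 comparisons, the endosome and phagosome list in 1 and the actin list in 3, with 0 calls kept under an estimated correlation.

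Fc beads were set against avidin beads at the same time, which compares the Fc coat with the avidin coat. No group had bare beads and the number of beads taken up was not measured, so ligand and bead were not fully separated. At 30 min, Cxcl2 was 4.59-fold higher with Fc than with avidin beads (log2 2.20 ± 0.16, adjusted p = 9.45e-05), Egr2 was higher by 1.51 ± 0.19 (adjusted p = 0.0183) and Ccl7 by 1.43 ± 0.17 (adjusted p = 0.00459). Of 14 chemokines 2 rose (5 over the list alone, median log2 0.42, camera adjusted p = 3e-07). Of 12 members of the cytokine list 0 passed (4 over the list alone, camera adjusted p = 0.00201). With an estimated correlation both lists stood at adjusted p = 0.0954. A fit on the slide run that holds both groups gives the same differences by construction. With fewer arrays the calls were lost there, at 2.20 ± 0.15 for Cxcl2 (adjusted p = 0.0839), 1.43 ± 0.18 for Ccl7 (0.284) and 1.51 ± 0.18 for Egr2 (0.2). On these same differences, chemokines and cytokines kept their camera calls (adjusted p = 6.99e-07 and 0.00226). In limma 6 of 22468 features passed, all higher, and in that slide run alone 0 (686 at an unadjusted p under 0.05). The count was 18 and 2 without avidin replicates 1 and 2, 16 and 23 without Fc replicates 1 and 2, and 18 without the dim array. Cxcl2 kept its call with each array left out, Ccl7 lost it without avidin replicate 2 (adjusted p = 0.104), and Egr2 without either avidin array or Fc replicate 2 (up to 0.116).

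At 60 min, Cxcl2 was 5.97-fold higher with Fc than with avidin beads (log2 2.58 ± 0.20 on 1 avidin array that was not the dim one, adjusted p = 5.89e-05), and Ccl7 was higher by 2.06 ± 0.17, Ccl2 by 1.46 ± 0.13 and Egr2 by 2.35 ± 0.24 on 1 Fc array. Plk2, a stress-responsive kinase, was higher by 0.95 ± 0.12, Atf3 by 1.22 ± 0.16 and Rgs1, a regulator of G-protein signalling, by 1.23 ± 0.13, at least 1.87-fold since its avidin spots were at background. Tnf (1.68 ± 0.20) and Ccl3 (1.65 ± 0.19) had their avidin value on the dim array alone. Of 12 members of the cytokine list, which includes Ptgs2, 2 rose (8 over the list alone). The list kept its camera call with an estimated correlation (adjusted p = 2.24e-05, then 0.0272). Of 22 immediate-early genes 4 rose (9 over the list alone; camera adjusted p = 1.24e-05), and of 14 chemokines 5 rose (6 rose and 1 fell over the list alone; 0.000263). With an estimated correlation both stood at adjusted p = 0.268. Camera called 7 lists upward in all, and only the cytokine list kept the call. Fc and avidin beads at 60 min lay in different slide runs, so coat and run could not be told apart at that time. In limma 83 of 22228 features passed, 73 higher and 10 lower, and 33 of them had their avidin value on the dim array alone. Without the dim array 29 passed, 22 of which were among the 83, and without avidin replicate 2 3180 did. The calls of Cxcl2, Ccl7, Ccl2, Egr2, Plk2, Atf3 and Rgs1 were kept in each leave-one-out fit that gave them a value, and Cxcl2 and Egr2 could not be tested without their lone avidin and Fc array.

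LPS and avidin beads lay in different slide runs at both times, so ligand and run could not be told apart. At 30 min they differed in Med11 (-6.80 ± 0.20, at least 76.4-fold lower with LPS beads). It was the 1 feature of 22269 past the threshold in limma, and it rested on the single background spot described above. The count was 0 without LPS replicate 1 (which leaves Med11 without a value), 15 without LPS replicate 2, 10 and 2 without avidin replicates 1 and 2, and 7 without the dim array. At 60 min, Tnf was higher with LPS than with avidin beads by 1.17 ± 0.17 (adjusted p = 0.0295), with the avidin value on the dim array, and lost the call without LPS replicate 2 (adjusted p = 0.141). Crybb2, a crystallin gene, fell by 0.76 ± 0.13 on the log2 scale. In limma 32 of 22389 features passed, 29 higher and 3 lower, 25 of them with an avidin value on the dim array alone. Without the dim array 0 passed (1029 at an unadjusted p under 0.05), Crybb2 included in the loss (adjusted p up to 0.392), and without avidin replicate 2 2654 did. No list was called by camera at either time.

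Mannan and avidin beads also lay in different slide runs at both times, so ligand and run could not be told apart. At 30 min they differed in 3 of 22420 features, all higher with mannan beads. Among these were Psmc3ip, a meiotic recombination factor (0.84 ± 0.11), and Capn5, a calpain protease (0.73 ± 0.10, at least 1.33-fold). Both lost the call without mannan replicate 1 or avidin replicate 2 (adjusted p up to 0.118), and Capn5 also without avidin replicate 1. The count was 8 without avidin replicate 1, 23 and 25 without mannan replicates 1 and 2, and 30 without the dim array. At 60 min, Tle6 was higher by 2.28 ± 0.32 (at least 4-fold, adjusted p = 0.00914) and Rgs1 by 0.88 ± 0.13 (at least 1.46-fold, with its avidin spots at background), while Crybb2 fell by 0.91 ± 0.13 and H1f2, a linker histone, by 0.67 ± 0.11 on the log2 scale. In limma 43 of 22240 features passed, 30 higher and 13 lower, 21 of them with an avidin value on the dim array alone. Without the dim array 1 passed, 0 of it shared with the 43, and these 4 genes lost their calls, Tle6 also without mannan replicate 1 (adjusted p up to 0.0952), Crybb2 without mannan replicate 1 (up to 0.0952) and H1f2 without either mannan array (up to 0.189). Without avidin replicate 2 the count was 3171, and without mannan replicates 1 and 2 it was 25 and 88. No list was called by camera at either time.

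An F-test over the 4 bead types asked where the bead groups differed at all. At each time these groups lay in 3 slide runs, so the test could not separate ligand from run. Only avidin and Fc beads at 30 min, and LPS and mannan beads at 60 min, shared a run. At 30 min, Cxcl2 (F = 85.2, adjusted p = 0.000105), Egr2 (F = 31.1) and Ccl7 (F = 28.1) differed, with the highest mean for Fc beads, and Med11 differed (F = 499) on the single background spot. Of 11 features of 22030 that passed, Fc beads had the highest mean in 7 and mannan beads in 4. The 7 include Med11, which averaged 12.9 with Fc, 12.8 with avidin and 12.9 with mannan beads and was low only with LPS beads. At 60 min, Cxcl2 (F = 123, adjusted p = 2.12e-05), Ccl7 (F = 63.4), Ccl2 (F = 48.7) and Egr2 (F = 37.8) differed in the same direction, Tle6 (F = 27.3) was highest with mannan beads, and Hcls1, an actin-regulating substrate of Src-family kinases (F = 82.2), was lowest on the dim array and lost its call with the contaminated spots kept (F = 2.62, adjusted p = 0.471). Of 86 of 21829 features, Fc beads had the highest mean in 50, mannan beads in 15, avidin beads in 12 and LPS beads in 9. At 30 min Egr2 lost its call without either Fc array (adjusted p up to 0.105) and Ccl7 without either Fc array or avidin replicate 2 (up to 0.0811). At 60 min Tle6 lost it without mannan replicate 1 (0.0531). The count at 30 min was 76 without the dim array, 17 without LPS replicate 2, 23 without Fc replicate 2, and 21 and 29 without mannan replicates 1 and 2. At 60 min it was 41 without the dim array, 2478 without avidin replicate 2, 51 without Fc replicate 2 and 44 without mannan replicate 1.

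From 30 to 60 min, Chac1 rose with every bead type, by 1.49 ± 0.15 with avidin (adjusted p = 0.000421), 1.75 ± 0.15 with Fc (0.000227), 1.69 ± 0.15 with LPS (0.00017) and 2.10 ± 0.15 with mannan beads (2.05e-05). The 4 calls were kept with each array left out. Only avidin and mannan beads had both times in 1 slide run. The changes with Fc and LPS beads could not be told apart from a run difference. For avidin and mannan beads, a fit on their slide run gives the same change by construction. The call was kept for mannan beads (2.10 ± 0.12, adjusted p = 0.000248) and lost for avidin beads (1.49 ± 0.16, adjusted p = 0.119). At 60 min Chac1 stood within 0.60 of untreated cells with every bead type (mannan 0.60 ± 0.15, adjusted p = 0.46). With Fc beads Cd83 rose by 1.65 ± 0.14 and Fzd2, a Wnt receptor, by 1.27 ± 0.13, each on 1 array at 60 min. With avidin beads Klf11 rose by 0.75 ± 0.12, while Id1 fell by 0.91 ± 0.15 and Ier3 by 0.84 ± 0.15 on the log2 scale; Klf11 and Id1 lost their calls without the dim array, and all 3 without either avidin array at 30 min (adjusted p up to 0.276) and within the slide run.

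The unfolded protein and integrated stress response list rose with time for mannan (1 of 16 past the threshold; 5 rose and 1 fell over the list alone; camera adjusted p = 0.000496), Fc (1 of 15, 4 over the list alone; 0.00316) and LPS beads (1 of 16, 1 over the list alone; 0.0161). With an estimated correlation these stood at adjusted p = 0.365, 0.581 and 0.974. Camera called 3 more lists upward with time for Fc beads (NF-kappaB targets, antigen presentation and actin) and 2 more for mannan beads (interferon response and antigen presentation), and 0 of them kept the call with an estimated correlation (adjusted p = 0.581 and 0.365). Within the slide run of mannan beads, the stress response and antigen presentation lists kept their camera calls (adjusted p = 0.00204 and 0.0351) and the interferon list lost its own (0.0621). In limma 59 of 22473 features passed for avidin beads (10 higher, 49 lower), 8 of 22229 for Fc (5 and 3), 7 of 22183 for LPS (3 and 4) and 5 of 22195 for mannan beads (3 and 2). For avidin beads the count was 8 without the dim array, 2478 without replicate 2 at 60 min, 13 without replicate 2 at 30 min, and 0 within the slide run (1107 at an unadjusted p under 0.05). For Fc beads it was 27 and 18 without replicates 1 and 2 at 60 min, 19 and 53 without replicates 1 and 2 at 30 min, and 78 without the dim array. For LPS beads it was 16 and 18 without replicates 1 and 2 at 60 min, 15 without replicate 2 at 30 min and 11 without the dim array. For mannan beads it was 9 and 40 without replicates 1 and 2 at 30 min, 10 and 45 without replicates 1 and 2 at 60 min, and 27 without the dim array.

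The change with time was then compared between ligands. For Fc and LPS beads the times lay in different slide runs, so these contrasts could not separate the ligand from a run difference. Hcls1 changed differently with Fc (2.46 ± 0.20), LPS (2.07 ± 0.20) and mannan beads (2.12 ± 0.22) than with avidin beads, with its avidin value at 60 min on the dim array alone. With the contaminated spots kept, a setting chosen after the data were seen, the Hcls1 values were 1.26, 0.95 and 0.95 with an SE of 0.57, and the 3 calls were lost (adjusted p = 0.499, 0.805 and 0.781). Cd83 changed differently with Fc beads (1.62 ± 0.18, adjusted p = 0.00373) and Med11 with LPS beads (modelled as 6.71 ± 0.26 on the single background spot, so of no exact size; from 30 to 60 min of LPS beads it was at least 71.2-fold higher). In limma 15 of 22083 features passed for Fc, 10 of 22039 for LPS and 8 of 22041 for mannan beads, and 11, 8 and 7 of these had their avidin value at 60 min on the dim array alone. The 6 features called in all 3 contrasts were all of that kind, and they included Hcls1, the small GTPase gene Arf2, the Golgi protein gene Glg1, the transcription factor gene Tfap4 and the ganglioside synthase gene B4galnt1. Camera called 6 lists upward for Fc against avidin beads, and 0 with an estimated correlation (adjusted p = 0.436 for each), and none for the other ligands. Without the dim array the counts were 4, 1 and 0 (limma), and without avidin replicate 2 at 60 min they were 1775, 903 and 1195.

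**Figure D3:**
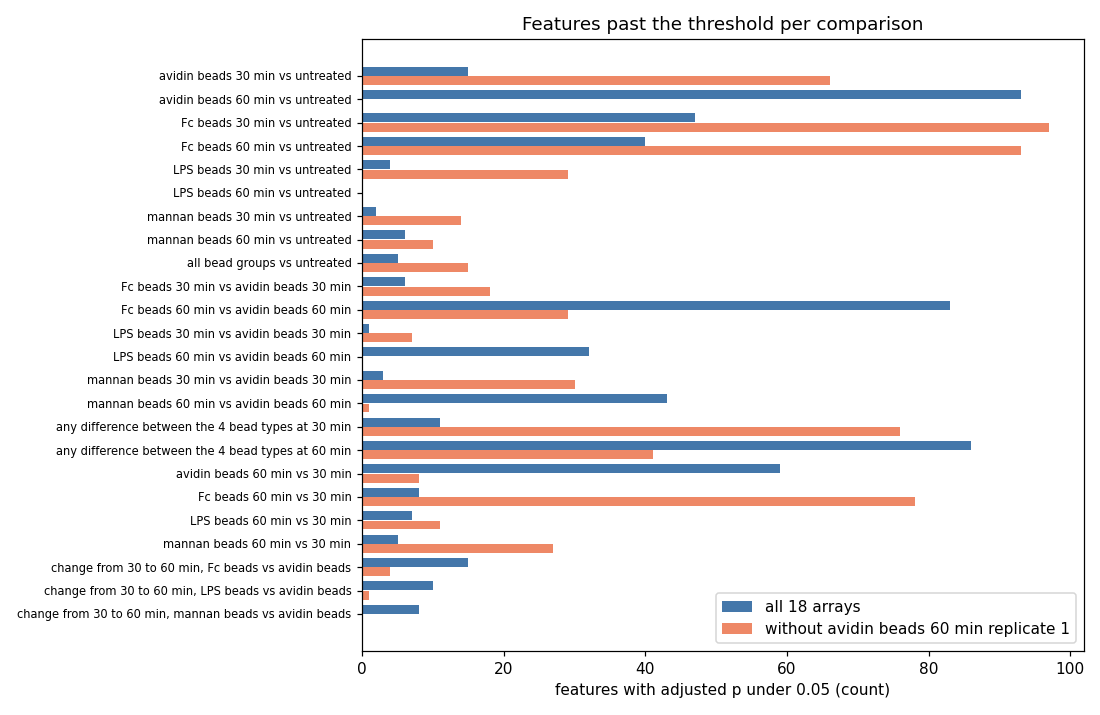
Number of features with an adjusted p under 0.05 in each of the 24 tests, for all 18 arrays (blue bars) and without replicate 1 of avidin beads at 60 min (orange bars). Avidin beads at 60 min against untreated cells go from 93 to 0 and Fc beads at 60 min against untreated cells from 40 to 93.

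For those contrasts of time courses, other single arrays moved the counts as well. For Fc beads the count was 26 and 25 without Fc replicates 1 and 2 at 60 min, and 24 and 7 without avidin replicates 1 and 2 at 30 min. For LPS beads it was 4 and 16 without LPS replicates 1 and 2 at 30 min, 17 without LPS replicate 2 at 60 min and 6 without avidin replicate 2 at 30 min. For mannan beads it was 3 and 22 without mannan replicates 1 and 2 at 30 min, 5 and 21 without mannan replicates 1 and 2 at 60 min, and 3 without avidin replicate 2 at 30 min.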

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

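Differences between bead types or between time courses are collected here, and the medians over called features, and the use of planned contrasts, F-tests and leave-one-out fits to weigh explanations, were tests chosen only after the result was seen. The bootstrap intervals of these medians resample features, not arrays, so they do not measure the spread between cell samples. The bead types differed in 11 features at 30 min and in 86 at 60 min by the F-test. The change from 30 to 60 min differed from that with avidin beads in 15 features for Fc, 10 for LPS and 8 for mannan beads. Med11 was behind 1 of the 11, on the single LPS array described in the report.

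The first pattern is the higher chemokine and cytokine transcripts with Fc beads. Fc beads at 60 min were run on other slides than untreated and avidin-bead cells, but the 30 named or unnamed features called higher there had a median log2 of 0.448 (95 percent bootstrap interval 0.305 to 0.645; 25 of 30 above 0) for Fc against avidin beads at 30 min, within 1 slide run, which argues against a slide-run difference as the whole cause if the slide numbers mark the runs. Endotoxin carried by the Fc beads could raise the same genes. Their median with LPS beads at 60 min was 0.191 (interval 0.108 to 0.285) against 1.04 with Fc beads. The features were chosen on that Fc value, which selection pushes upward. Both values share the untreated arrays, which can lift the LPS median above 0 without any change. The amount of LPS on either bead is not known either, so this explanation stays open. Signalling through Fc receptors remains the biological hypothesis, and the number of beads taken up, which may differ between ligands, was not measured here.

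The second pattern is the set of features called with avidin beads at 60 min, a group that also enters the 3 time-course contrasts, where 11 of 15, 8 of 10 and 7 of 8 features had their avidin value at 60 min on the dim array alone. With the dim array as the only avidin array at 60 min 3479 features passed against untreated cells, and with the other array alone 0 passed in limma (2299 at an unadjusted p under 0.05), which fits an effect of that 1 array. A slide-run difference cannot be told apart here: within the run that holds both times, the called features moved in the called direction by a median of 0.507 (interval 0.447 to 0.674), against 0.92 for 60 min against untreated cells in another run, but the dim array takes part in both values. At 30 min of avidin beads against untreated cells, without that array, the same features had a median of 0.42 (interval 0.302 to 0.476; 76 of 93 in the called direction), but that value shares the untreated arrays and the difference in slide run with the call. How much of the 60 min calls is an effect of avidin beads therefore stays open.

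The third pattern is the lower Chac1 at 30 min with every bead type and its return by 60 min. Avidin beads at 30 and 60 min shared 1 slide run and differed by 1.49 on the log2 scale, higher in 2 of 2 arrays, which argues against a slide-run difference as the cause if the slide numbers mark the runs. No difference between the ligands was called in the F-test at 30 min (adjusted p = 0.851), which does not show that they were alike. Fresh serum-free medium given with the beads may lower it as well as uptake of any bead. Whether untreated cells had the same change of medium is not given in the sources used here, so this stays open.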

How the results depend on the processing

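Of these settings, keeping the contaminated spots and leaving the dim array out of comparisons it does not belong to were chosen only after the data were seen. Signal over background limits the weak transcripts: the dim array had 49.6 percent of its probes above background. Unless a reason is given, the cause was not tested.

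Counts of features past the threshold moved by more than 1.5 times as follows, with the bead groups against untreated cells unless another group is named. With an offset of 16 they were 6 for avidin 30 min, 55 for avidin 60 min, 1 for mannan 30 min, 1 for mannan 60 min, 2 for all beads, 4 for LPS and 1 for mannan against avidin at 30 min, 4 for the F-test at 30 min, 1 for mannan 60 against 30 min and 4 for the mannan time-course contrast. With median scaling they were 8 and 308 for avidin 30 and 60 min, 31 for Fc 30 min, 7 for mannan 30 min, 118 for avidin 60 against 30 min, and 35, 27 and 16 for the Fc, LPS and mannan time-course contrasts. Median scaling moved the median of all genes to -0.123 for avidin 60 min and to -0.151 for avidin 60 against 30 min, and 14.6 percent of the calls for avidin 60 min were then higher, against 28.

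With the deposited normalised intensity the counts were 3 and 28 for avidin 30 and 60 min, 28 and 22 for Fc 30 and 60 min, 5 for LPS 60 min, 1 and 0 for mannan 30 and 60 min (limma; 1107 at an unadjusted p under 0.05), 2 for all beads, 2, 3 and 1 for Fc, LPS and mannan against avidin at 30 min, 19 for mannan against avidin at 60 min, 6 and 57 for the F-tests at 30 and 60 min and 1 for mannan 60 against 30 min. With the GeneSpring values they were 5 and 30 for avidin, 26 and 24 for Fc, 6 for LPS 60 min, 1 for mannan 60 min, 3 for all beads, 2 and 3 for Fc and LPS against avidin at 30 min, 22 for mannan against avidin at 60 min, 6 for the F-test at 30 min and 2 for mannan 60 against 30 min. Of the 47 calls for Fc 30 min and the 40 for Fc 60 min, 24 and 19 were shared with the normalised intensity.

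With no filter they were 7 and 33 for avidin 30 and 60 min, 5 for LPS 60 min, 7 and 15 for mannan 30 and 60 min, 10 for all beads, 2 and 5 for LPS and mannan against avidin at 30 min, 16 for LPS against avidin at 60 min, 57 for the F-test at 60 min, and 17, 11 and 16 for avidin, LPS and mannan 60 against 30 min. With spots above background on all 18 arrays, which leaves fewer genes, they were 23 and 39 for avidin 30 and 60 min, 19 and 23 for Fc, 15 for LPS 30 min, 0 for mannan 60 min (limma; 290 at an unadjusted p under 0.05), 1 and 0 for Fc and LPS against avidin at 30 min (364 unadjusted for LPS), 9, 0 and 2 for Fc, LPS and mannan against avidin at 60 min (583 unadjusted for LPS), 2 and 11 for the F-tests, 10, 4 and 2 for avidin, Fc and mannan 60 against 30 min, and 0 for each time-course contrast (678, 319 and 340 unadjusted).

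With replicate number as a block they were 1 for LPS 60 min and 5 for the mannan time-course contrast. With an intensity trend and robust estimation they were 32 and 143 for avidin 30 and 60 min, 16 and 1 for LPS 30 and 60 min, 7 and 3 for mannan 30 and 60 min, 12 for all beads, 14 and 7 for Fc and mannan against avidin at 30 min, 26 for the F-test at 30 min, 25 for Fc 60 against 30 min, and 31 and 13 for the Fc and mannan time-course contrasts. Within slide run 2, which leaves fewer samples, they were 0 for Fc against avidin at 30 min (limma; 686 unadjusted) and 0 for avidin 60 against 30 min (1107 unadjusted). Within slide run 3 they were 5 and 3 for mannan 30 and 60 min and 9 for mannan 60 against 30 min. With the contaminated spots kept they were 17 for LPS 30 min, 6 and 3 for mannan 30 and 60 min, 13 for all beads, 2 and 0 for LPS and mannan against avidin at 30 min (limma; 2888 unadjusted for mannan), 40, 0 and 13 for Fc, LPS and mannan against avidin at 60 min (2537 unadjusted for LPS), 5 and 44 for the F-tests, 11 and 12 for avidin and mannan 60 against 30 min, and 4, 1 and 0 for the time-course contrasts (1509 unadjusted for mannan).

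With 1 array left out, counts against untreated cells ranged over 4 to 66 and 0 to 3479 for avidin 30 and 60 min, 17 to 97 and 16 to 93 for Fc, 4 to 29 and 0 to 12 for LPS, 6 to 28 and 2 to 35 for mannan, and 3 to 30 for all beads. Against avidin they ranged over 2 to 23 and 29 to 3180 for Fc, 0 to 15 and 0 to 2654 for LPS, and 3 to 30 and 1 to 3171 for mannan. The F-tests ranged over 10 to 76 and 41 to 2478, the change from 30 to 60 min over 8 to 2478 for avidin, 18 to 78 for Fc, 6 to 18 for LPS and 9 to 45 for mannan, and the time-course contrasts over 4 to 1775, 1 to 903 and 0 to 1195. The highest values of the comparisons with avidin at 60 min came without avidin replicate 2, which leaves the dim array.

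Gene results reversed only among values that had not passed the threshold, and mostly for avidin beads at 60 min against untreated cells. There, Ccl7 became -0.22 with median scaling, -0.027 with the normalised intensity, -0.026 with the GeneSpring values and -0.21 without the dim array (range with 1 array left out -0.21 to 0.26). Ccl3 became 0.33 with the normalised intensity and with the GeneSpring values, 0.039 with the contaminated spots kept and 0.063 without untreated replicate 1 (range -0.20 to 0.063). Ier3 became -0.043 with median scaling and -0.18 without the dim array (range -0.18 to 0.34). Chac1 became -0.17 with median scaling, -0.026 without the dim array and -0.048 without untreated replicate 1 (range -0.048 to 0.16). For LPS beads at 60 min, without untreated replicate 1, Chac1 became -0.051 (range -0.051 to 0.15) and Ccl2 0.023 (range -0.16 to 0.023). Of the 208 gene results, 176 kept both their direction and their side of the threshold with an offset of 16, 182 with median scaling, 146 with the normalised intensity, 168 with no filter and 166 with the contaminated spots kept. The camera list results moved in 0 of 22 comparisons with an offset of 16 and in 11 with median scaling. They moved in 10 with the normalised intensity, 9 with the GeneSpring values and 8 with no filter. With spots above background on all 18 arrays they moved in 16. Replicate number as a block, or keeping the contaminated spots, moved 3. An intensity trend, or leaving out the dim array, moved 2. Without LPS replicate 2 at 60 min they moved in 4 of 5, and without Fc replicate 1 at 60 min in 0 of 5.

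Slide run as a random block could not be fitted for the group contrasts, since each group lies in 1 run, and a scan batch was not run, since the files give no scan batch.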

Other observations

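The contrasts over pooled bead groups in this part, and all tests of them, were chosen only after the results of the report were seen.

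Over the 4 bead types, 8 arrays at 60 min were set against 8 at 30 min. Chac1 rose by 1.76 ± 0.10 (adjusted p = 4.94e-09), with each array at 60 min above each at 30 min. Klf11, a Krüppel-like factor induced by TGF-beta, rose by 0.62 ± 0.07, Gadd45a, a growth arrest and DNA damage gene, by 0.60 ± 0.11, Klf10 by 0.54 ± 0.09 and Tgfb3, a TGF-beta ligand, by 0.46 ± 0.07. Id1 fell by 0.93 ± 0.11 on the log2 scale and Jun by 0.65 ± 0.12. Bbc3, the proapoptotic protein PUMA (0.43 ± 0.09, adjusted p = 0.049), stood at 0.0538 without the dim array, and Ier3 (-0.72 ± 0.15, adjusted p = 0.049) at 0.0556. In limma 73 of 22631 features passed, 42 higher and 31 lower. The count was 79 without the dim array (61 shared), 71 with slide run as a block (55 shared), and 39 without LPS replicate 2 at 30 min. In each run the arrays at 60 and 30 min came partly or wholly from different bead types, so the block mixes time with bead type. The unfolded protein and integrated stress response list was shifted upward (3 of 16 rose; camera adjusted p = 0.00056, and adjusted p = 0.59 with an estimated correlation). Of 100 splits of the 16 bead arrays into 8 and 8, 1, the real one, gave as many features (73, highest other 1). Such splits part the replicates of a group. Of the 35 splits that keep the 8 bead groups whole, 1, the real one, gave as many (highest other 3). The contrast was picked after its genes were seen to move with time, so this count does not exclude chance.

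Fc beads over both times were set against the other 3 bead types, 4 arrays against 12. Cxcl2 was higher by 2.28 ± 0.13 (adjusted p = 1.31e-08), Egr2 by 1.77 ± 0.16, Ccl7 by 1.51 ± 0.17 and Ccl3 by 1.00 ± 0.14. Nr4a1, an orphan nuclear receptor, was higher by 1.10 ± 0.17, Csf2 by 0.96 ± 0.15 and Plk2 by 0.60 ± 0.10. With slide run as a block, Cxcl2 stood at 2.26 ± 0.13 (adjusted p = 3.37e-07) and Csf2 at adjusted p = 0.0512. Within run 1, Cxcl2 differed by 2.34 and within run 2 by 2.19. The run 1 value sets Fc beads at the later time against LPS beads at the earlier time. The run 2 value sets Fc beads at the earlier time against avidin beads at both times. Both values, and the block, therefore mix bead type with time. Of 14 chemokines 4 rose (camera adjusted p = 7.39e-11). Of 12 members of the cytokine list 2 rose, Csf2 and the enzyme gene Ptgs2 (camera adjusted p = 1.69e-08). Both lists kept their calls with an estimated correlation (adjusted p = 0.0291 and 0.00511). In limma 19 of 22520 features passed, 15 higher and 4 lower, with 13 under the slide-run block (12 shared), 25 without the dim array and 9 without Fc replicate 2 at 60 min. Of 100 splits into 4 and 12, 1, the real one, gave as many (19, highest other 4). Of the 28 splits that keep the bead groups whole, 2 gave as many, and the 2 mannan groups against the rest, which share a slide run, gave 50, so chance splits of whole groups cannot be excluded for this count.

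A probe without a symbol, chosen after its values were seen, moved with Chac1 at 30 min. Against untreated cells it stood at -1.48 ± 0.12 with avidin (adjusted p = 0.00101), -1.87 ± 0.12 with Fc (3.62e-05), -1.63 ± 0.12 with LPS (0.000165) and -1.07 ± 0.15 with mannan beads on 1 array (0.0538). At 60 min it stood at -0.07 with avidin, -0.23 with LPS and -0.31 with mannan beads, and it had no value with Fc beads.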
